A study of Arabidopsis thaliana with 6 samples.

How the data were processed

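RNA of Arabidopsis thaliana seedlings was measured on 6 Affymetrix expression arrays, 2 from wild type (WT) and 2 from each of the mutants bin4-1 and bin4-2. Groups were taken from the genotype given in the labels. Replicate numbers only name the arrays, and nothing in the labels says that the 2 arrays of a group came from separate plant cultures. The p-values of single genes therefore measure the spread between these arrays, which may be technical.

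Per the labels, total RNA was labelled with biotin by the manufacturer's standard protocol. The deposited values are intensities that the authors computed with RMA (robust multi-array average, which corrects background, equalises the arrays and summarises the probes of each probe set), per the submitters' processing notes. The RMA version and settings are not given in the sources used here. The deposited values lie on a linear scale, with a median intensity between 26.1 and 27.0 on each array, so log2 was taken before any other step. The sorted log2 values of any array differed from those of the mean array by at most 0.21. For arrays, depth is not a count of molecules, and the number of arrays limits the precision. Chromatin and sequencing experiments mentioned in the study's design text were not analysed here.

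The array holds 22810 probe sets, of which 64 are manufacturer controls and were left out of the gene tests. The platform annotation used here lists exactly 1 gene for 13513 probe sets, several for 503 and none for 8730 others, which are unnamed here. Of the first, 13436 were matched by gene identifier to the RefSeq gene table (assembly TAIR10.1), used for current names and the order of loci only, and 77 kept the name of the platform. No gene was named from a probe set with several genes. For the 146 genes with more than 1 probe set the one with the highest mean over the 6 arrays was kept, which left 13356 genes. No background level was set, so changes to or from very low values are lower bounds.

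Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values, 3 group means, all 6 arrays in 1 fit). The fit had 3 residual and 8.25 prior degrees of freedom. Contrasts were each allele against WT, bin4-2 against bin4-1, and the mean of both alleles against WT. The tests were two-sided, with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05 without a fold threshold. Each log2 change is given with limma's standard error (SE). Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Simulated arrays used the WT means and the spread of each gene from the limma fit. In bin4-1 alone, 50 genes each were changed 1.5-, 2-, 4- and 8-fold. The bin4-1 against WT contrast over 13356 genes recovered 90% of those changed 1.5-fold and 100% of those changed 2-fold. It made 9 calls among unchanged genes. For bin4-2 against bin4-1 the recovery was 88% and 100%, with 10 such calls. The Benjamini-Hochberg cutoff depends on how many genes change, so these rates do not carry over to the measured contrasts. Between the alleles, the smallest measured log2 change that was called was 0.58 in size.

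Before the data were examined, 20 gene lists with 261 members were fixed, along with windows around the centromeres and the rule for naming genes. The alternatives were fixed then too, apart from those named below as added later. Only 32 list members are named by a probe set here, no list is close to complete, and any statement on a list covers its measured members only. Lists of gene-silencing, floral and senescence genes had 0 measured members. Lists with at least 3 members were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. A further 36 lists were added after the annotation and the correlations between arrays had been seen, and before any expression test: organelle-encoded genes, histones, peroxidases, ribosomal proteins, pseudogenes, further DNA-damage and heat-shock genes, and 25 families of at least 8 genes sharing a symbol. Benjamini-Hochberg adjustment was applied within the fixed lists, within the added lists and within the windows.

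The windows were set by locus number, which follows the order along a chromosome: AT1G31000 to AT1G48000, AT2G03600 to AT2G16600, AT3G27700 to AT3G47500, AT4G03400 to AT4G10200 and AT5G25600 to AT5G40200. They were tested with camera and with two-sided Fisher's exact tests of falls and rises against the other nuclear genes, adjusted over all window and pseudogene tests. Narrower windows inside these were fixed as an alternative: AT1G35000 to AT1G44500, AT2G04500 to AT2G13500, AT3G29500 to AT3G44500, AT4G04000 to AT4G08500 and AT5G27700 to AT5G36500.

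Named genes are the measured topoisomerase VI genes, the 8 largest rises and falls of each allele against WT and the 5 largest rises and falls between alleles, each with both arrays of 1 group beyond both of the other. They also include the 4 members of each fixed list with the largest mean change, called or not, and the 5 largest falls and rises in the windows. In added lists, the 3 members with the largest change were named after their values were seen. Overlaps of calls between alleles were set beside 20 simulations of unchanged groups and the product of the list sizes. Alternatives covered normalization, filters on dim genes, the choice of probe sets, a 2-fold threshold, the variance model, the arrays in the fit, the title suffix as a replicate block, and leaving out each array.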

Results

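The arrays compared the transcriptome of wild-type seedlings with that of plants carrying either of a pair of mutant alleles of BIN4, bin4-1 and bin4-2. BIN4 is a plant component of the topoisomerase VI complex, which passes DNA strands through each other and is needed for repeated rounds of genome replication without division. The series title places the arrays in a study of whether topoisomerase VI limits the spread of heterochromatin into islands of euchromatin. Each group held 2 arrays, 6 in all, with a median log2 intensity between 4.71 and 4.76. Arrays of 1 group correlated at 0.995 to 0.997 across probe sets, WT and mutant arrays at 0.905 to 0.916, and arrays of different alleles at 0.995 to 0.996. The first principal component held 91.5% of the variance and separated both WT arrays from all 4 mutant arrays.

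BIN4 itself (AT5G24630) was lower in both mutants, a weak check of the labels as far as its probe set reports on the mutated transcript. Lower values also passed the threshold for 3338 of the 13356 genes in bin4-1 and for 3555 in bin4-2. BIN4 was dim, with the 25th percentile of the 2 WT arrays at 3.32 and 3.34. Its mean log2 intensity was 3.86 ± 0.11 in WT, 3.33 ± 0.04 in bin4-1 and 2.98 ± 0.09 in bin4-2 (SD, n = 2 each). The BIN4 change was -0.53 ± 0.11 in bin4-1 (SE, limma adjusted p = 0.0015) and -0.87 ± 0.11 in bin4-2 (adjusted p = 3.18e-05). The alleles did not differ past the threshold at BIN4 (-0.34 ± 0.11, adjusted p = 0.444). Where the probe set lies relative to the mutations was not analysed here.

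In bin4-1 against WT, the 8 largest rises included genes of cell-wall breakdown, oxidases and calcium or receptor signalling, classes that were not tested as sets. PRX52, a secreted class III peroxidase, rose 36.3-fold (log2 5.18 ± 0.11, SE, adjusted p = 1.78e-10). ADPG1, a polygalacturonase that acts in cell separation, rose by 4.64 ± 0.12 on the log2 scale (adjusted p = 2.7e-10). The berberine-bridge-enzyme-like oxidase genes AT1G26420 and AT1G26390 rose by 4.66 and 4.61. AT3G47480, which encodes an EF-hand calcium-binding protein, rose by 4.57 ± 0.15. AT1G57630, a TIR-domain gene, rose by 4.48, AT1G35710, a leucine-rich-repeat receptor kinase gene, by 4.43, and AT5G52760 by 4.88.

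The largest falls in bin4-1 included genes of phospholipid synthesis, nitrate transport and the chloroplast. AT1G73600, a phosphoethanolamine methyltransferase gene of phosphocholine synthesis, was 21.5-fold lower (log2 -4.42 ± 0.12, SE, adjusted p = 3.02e-10). AT1G66100, a thionin gene, fell by 4.09 ± 0.18, and AT3G21670, the nitrate transporter NPF6.4, fell by 3.94 ± 0.10. AT2G04039, a subunit of the chloroplast NADH dehydrogenase-like complex, fell by 3.90 ± 0.17. MSRB6, a methionine sulfoxide reductase, fell by 3.70 ± 0.12, as did AT3G45160. AT1G78020 fell by 3.73 and AT2G36145 by 3.45. Across the 13356 genes, 6271 passed the limma threshold, 2933 higher and 3338 lower in bin4-1. Of these, 977 were higher and 922 lower by at least 2-fold, and 103 were higher and 21 lower by at least 8-fold. The median log2 change of all genes was -0.08, against which single changes are read. With the 5380 genes of a mean log2 of at least 5 alone, 3927 passed, 2149 higher and 1778 lower, while all probe sets gave 11846. That filter favours rises, since 4 of the 6 arrays averaged are mutant. A filter on the midpoint of the WT and mutant means, added after the results were seen, still kept more rises than falls. With calls from the fit of all genes it gave 1871 rises and 1764 falls in bin4-1, against 1985 and 1652 by the mean of 6 arrays. In bin4-2 it gave 1836 and 1796.

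bin4-2 against WT shared 6 of its 8 largest rises and 6 of its 8 largest falls with bin4-1. PRX52 rose by 5.11 ± 0.11 on the log2 scale (SE, limma adjusted p = 2.08e-10), AT5G52760 by 4.95 ± 0.16 and ADPG1 by 4.76 ± 0.12. AMY1, a secreted alpha-amylase, rose 24.4-fold (log2 4.61 ± 0.10), and AT1G10585, a basic helix-loop-helix gene, rose by 4.61 ± 0.11. The WT value of AT1G10585 was 2.47, below the 5th percentile of the WT arrays (2.63), so its change is read as a lower bound. With no background level set, the changes of AT1G26390 (2.80 in WT) and AT1G66100 (2.78 in bin4-1) are read in the same way. Both of these values lie above that percentile. AT1G57630, AT1G26390 and AT3G47480 rose by 4.64, 4.64 and 4.63. Among the falls, the thionin gene AT1G66100 changed by -3.80 ± 0.18, AT1G73600 by -3.63 ± 0.12, NPF6.4 (AT3G21670) by -3.38 ± 0.10 and MSRB6 by -3.18 ± 0.12. AT2G04039 changed by -3.14, AT3G46490 by -3.11, the glutaredoxin gene AT2G47880 by -3.04 and AT1G78020 by -2.87. In total 6377 genes passed, 2822 higher and 3555 lower, of which 951 and 876 changed by at least 2-fold. The median log2 change of all genes was -0.09. With genes of a mean log2 of at least 5 alone, 3934 passed, 2098 higher and 1836 lower, and all probe sets gave 12031.

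The changes in bin4-1 and bin4-2 ran in parallel. Both alleles passed in the same direction for 5576 genes, 2605 higher and 2971 lower, with 3 genes in opposite directions. Independent lists of these sizes would share 620 higher and 888 lower genes. Simulated unchanged groups against the shared WT arrays gave a mean of 0.1 and at most 2 shared genes in 20 simulations. Such groups have few calls by construction, so this does not show how far the shared arrays raise the overlap of lists this long. At least 2-fold changes in each allele were found for 1690 genes. The log2 changes correlated at 0.982 across genes, which are not independent replicates, against 0.499 in the simulations. Their covariance was 0.576 against a simulated 0.0071. With the WT arrays split 1 per allele, which was added after the results were seen, the covariance was 0.564 and 0.566 in the 2 possible splits and the correlation 0.943 and 0.948. This split removes the noise of a shared array, but not what the 2 WT arrays have in common, such as a culture or batch. The counts of shared genes were not split, since that leaves 1 control array each, and part of their excess may come from the shared arrays. The threshold was passed in bin4-1 alone by 692 genes and in bin4-2 alone by 798, but only 3 and 6 of these differed between the alleles. With a mean log2 of at least 5 the shared count was 3656, and with all probe sets 10673.

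**Figure D1:**
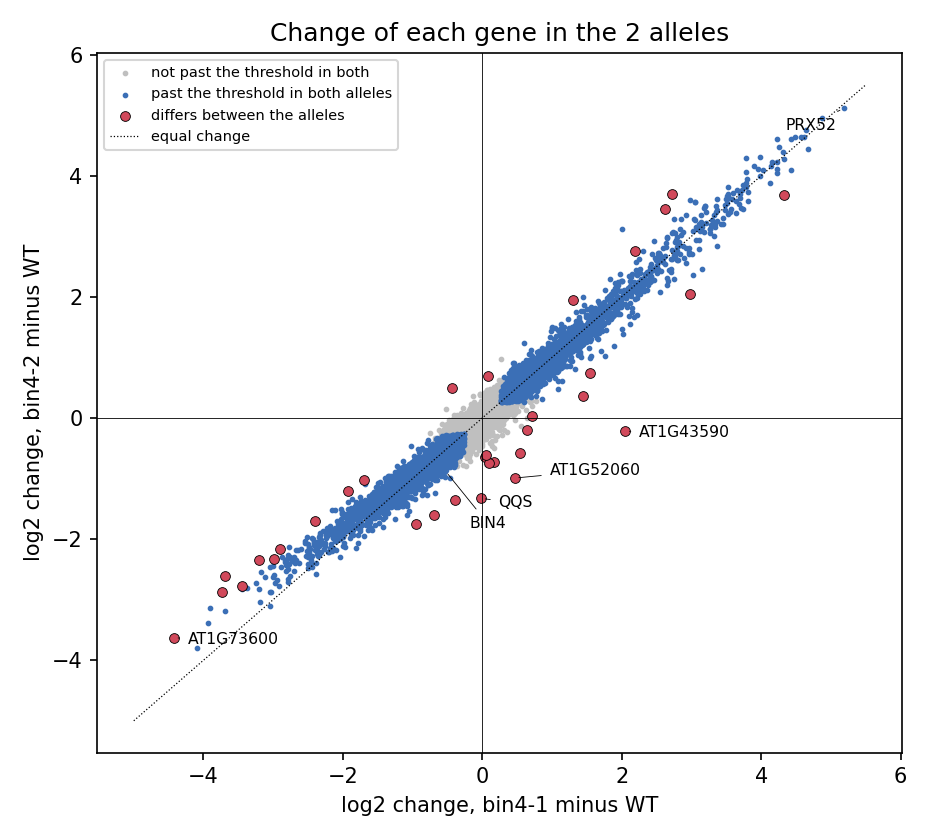
Log2 change of each of the 13356 genes in bin4-1 (horizontal) and bin4-2 (vertical) against WT, with 2 arrays per group. Blue points passed the threshold in both alleles, red points are the 33 genes that differed between the alleles, and the dotted line marks equal change.

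Nuclear photosynthesis genes fell in both alleles. All 5 measured members of the fixed list passed in each allele, also when adjusted over the list alone, and the list's median log2 change was -2.12 in bin4-1 and -1.81 in bin4-2. PRK, the phosphoribulokinase of the Calvin-Benson cycle, was 5.31-fold lower in bin4-1 and 4.13-fold lower in bin4-2 (log2 -2.41 ± 0.10 and -2.05 ± 0.10, SE). RCA, Rubisco activase, changed by -2.20 and -1.83, SBPASE, sedoheptulose bisphosphatase, by -2.12 and -1.81, and PORB, a protochlorophyllide reductase, by -1.24 and -1.35. camera gave an adjusted p of 1.96e-04 for the mean of both alleles (adjusted p = 0.0487 with an estimated correlation).

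Genes of the singlet-oxygen and general reactive-oxygen response rose. All 3 measured members passed in each allele, also when adjusted over the list alone, with a median log2 change of 2.81 in bin4-1 and 2.86 in bin4-2. AT3G28580, an AAA-ATPase gene used as a singlet-oxygen marker, rose by 3.02 ± 0.12 and 3.09 ± 0.12 (SE). STZ, the zinc-finger repressor also called ZAT10, rose by 2.81 and 2.86, and AT5G64870, a flotillin-like gene, rose by 2.36 and 2.23. camera gave an adjusted p of 2.76e-04 (adjusted p = 0.0487 with an estimated correlation).

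Of the flavonoid list, 3 genes were measured, of which 3 fell in bin4-1 and 2 in bin4-2, or 3 in each when adjusted over the list alone. DFR, the dihydroflavonol reductase of anthocyanin synthesis, fell by 1.32 ± 0.10 and 1.04 ± 0.10 (SE). UF3GT, a flavonoid glucosyltransferase, fell by 0.96 and 0.91. AT4G14090, an anthocyanin glucosyltransferase gene, changed by -0.51 in bin4-1 and -0.27 in bin4-2 (adjusted p = 0.00295 and 0.0714). camera gave an adjusted p of 0.0276, which was lost at adjusted p = 0.255 with an estimated correlation. Among genes with a mean log2 of at least 5, fewer than 3 flavonoid and fewer than 3 singlet-oxygen genes were left, so only the photosynthesis list was tested, and it passed. Without WT replicate 2, the mean change of AT4G14090 was -0.26 and did not pass (adjusted p = 0.0737).

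The other fixed lists had 1 or 2 measured members and were not tested as sets. In cell division, AUR1, an Aurora kinase of mitosis, changed by -0.95 and -1.14 in bin4-1 and bin4-2 (adjusted p = 8.64e-06 and 1.95e-06). The replication gene PRL, which encodes MCM7, changed by -0.46 in each allele, while ICU2, the catalytic subunit of DNA polymerase alpha, gave -0.05 and -0.18 without passing. Of the DNA-damage list, ATLIG4, DNA ligase IV, rose by 0.45 and 0.33, and AT4G32700, DNA polymerase theta, gave -0.07 and -0.04 without passing. Each of these counts was the same when adjusted over the list alone. Without WT replicate 1, the mean changes of ICU2 and AT4G32700 passed, at -0.37 and -0.33 (adjusted p = 0.0164 and 0.0411).

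Among the measured growth and epidermis genes, EXPA8, EXPA18 and TRY fell in both alleles. EXPA8, an expansin placed in the brassinosteroid list, changed by -3.04 ± 0.11 and -2.87 ± 0.11 (SE) in bin4-1 and bin4-2. The root-hair expansin EXPA18 changed by -1.09 and -1.46, and EXPA7 by -0.21 and -0.57 (adjusted p = 0.174 and 0.00163). TRY, a repressor of trichome formation, changed by -1.02 and -0.91. SIM, a cell-cycle inhibitor of trichomes, gave -0.32 and -0.25 without passing over all genes, and passed in bin4-1 when adjusted over the list alone. Its mean change over both alleles, -0.29 (adjusted p = 0.0523), passed over the list alone and under 6 alternatives, among them an intensity trend (adjusted p = 0.0218), quantile normalization (-0.34) and leaving out WT replicate 2 (-0.49). Without that same array the mean change of EXPA7 was -0.29 and did not pass (adjusted p = 0.0683).

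Stress and metabolic genes moved in different directions. SAG101, a partner of EDS1 in defence signalling, rose by 1.32 and 1.47 in bin4-1 and bin4-2, and the defensin PDF1.2 by 0.60 and 1.23. THI2.1, a thionin of the jasmonate list, gave 0.37 and 0.22 (adjusted p = 0.0476 and 0.214), and its mean over both alleles (0.30, adjusted p = 0.0589) passed over the list alone, after quantile normalization (0.37) and without bin4-1 replicate 1 (0.35) or bin4-2 replicate 2 (0.40). ATHSP22.0, a small heat-shock protein, rose by 0.53 in each allele. COR15A and COR47, both cold-induced, fell by 2.15 and 0.61 in bin4-1 and by 1.52 and 0.56 in bin4-2. BCAT4 and AT2G31790, both of glucosinolate synthesis, fell by 1.87 and 1.35 in bin4-1 and by 1.35 and 0.95 in bin4-2. The clock gene GI gave -0.12 and -0.22, and the embryogenesis gene M17 gave -0.00 and -0.08, without passing. Counts for each allele within these lists were the same when adjusted over the list alone.

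**Figure D2:**
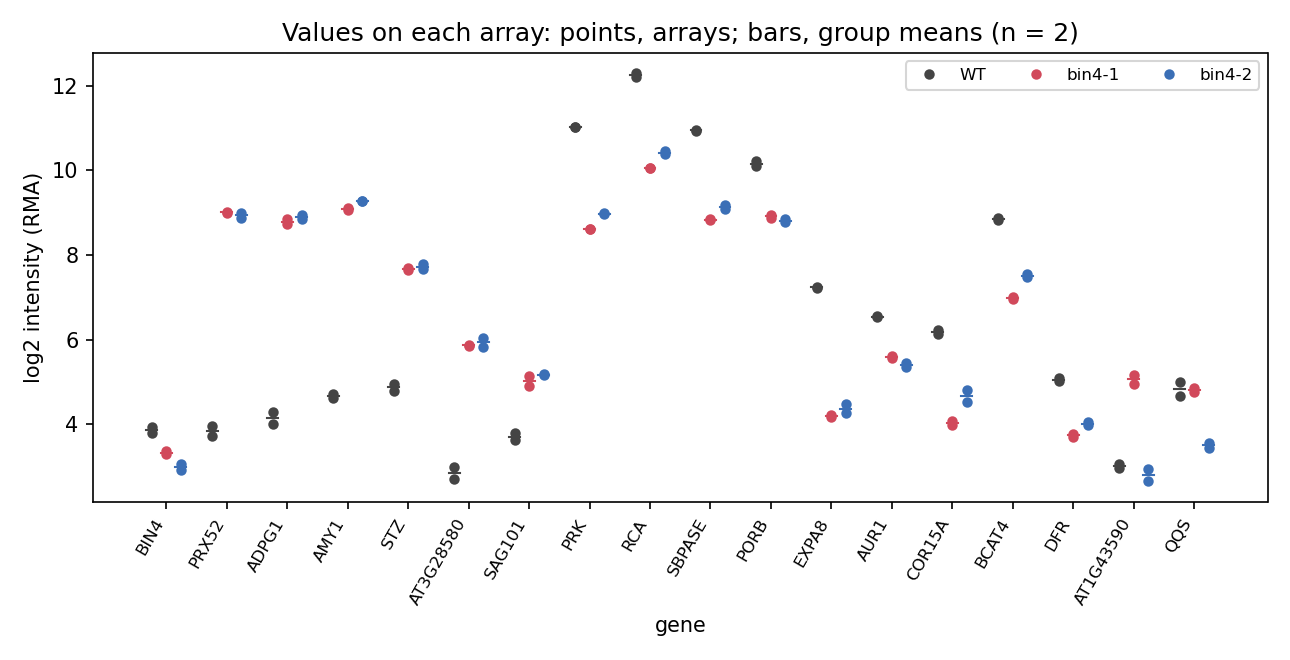
Log2 intensity of 18 named genes on each array, with WT in grey, bin4-1 in red and bin4-2 in blue; points are arrays and bars are group means (n = 2). The photosynthesis genes PRK, RCA, SBPASE and PORB lie lower in all mutant arrays than in WT, and PRX52, ADPG1, AMY1 and STZ lie higher.

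Transcripts encoded in the plastid genome fell with the nuclear photosynthesis genes. Of 69 plastid-encoded genes in an added list, 55 were lower and 0 higher in the mean of both alleles (57 lower when adjusted over the list alone), with a median log2 change of -0.58. Over all 13356 genes, 3852 were lower and 3097 higher in that mean. psbC, a core antenna protein of photosystem II, changed by -1.50 ± 0.12 in bin4-1 and -1.14 ± 0.12 in bin4-2 (SE), and ndhJ, a subunit of the plastid NADH dehydrogenase-like complex, by -1.40 and -1.18. psbA changed by -1.19 and -1.07, and the plastid RNA polymerase gene rpoC2 by -0.90 and -0.92. camera gave an adjusted p of 2.35e-07, lost at adjusted p = 0.633 with an estimated correlation. Its photosynthesis, gene-expression and NADH-dehydrogenase subsets gave 27 of 33, 14 of 20 and 9 of 10 genes lower, or 28, 14 and 9 when adjusted over each list alone. Their adjusted p values were 6.69e-05, 0.00657 and 0.00988, each 0.633 with an estimated correlation. The plastid genes varied together between arrays, with an estimated correlation of 0.521, and the median plastid gene was higher on replicate 1 than on replicate 2 by 0.20 in WT, 0.16 in bin4-1 and 0.26 in bin4-2.

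The added lists called higher were those of autophagy, DNA-damage, histone and heat-shock genes. Of 8 ATG genes, which act in autophagy, 7 rose in the mean of both alleles, among them ATG8H (1.81 ± 0.11 in bin4-1 and 2.02 ± 0.11 in bin4-2, SE) and ATG8B (1.82 and 1.83). Of 7 further genes induced by radiation or DNA breaks, 4 rose, including AT5G60250 (3.45 and 3.30) and AT2G18600 (3.14 and 3.17). camera gave an adjusted p of 7.78e-04 for each of these lists, lost at adjusted p = 0.489 with an estimated correlation. Of 9 histone genes, 4 rose in the mean of both alleles, led by AT3G53650 (2.83 and 3.12) and AT3G09480 (2.63 and 2.88), both H2B genes. Its adjusted p of 0.00988 was lost at adjusted p = 0.489 with an estimated correlation. Of 9 heat-shock genes, 7 rose, including AT5G51440 (2.22 and 2.06) and Hsp70-2 (2.12 and 1.89), and 2 fell, including AT4G21870 (-2.71 and -2.52). That list's adjusted p was 0.0121 and was likewise lost at adjusted p = 0.489 with an estimated correlation. Counts for the mean of both alleles in these 4 lists were the same when adjusted over each list alone.

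Expansins of the EXPA family, which loosen cell walls, were lower for 7 of 10 measured genes and higher for 0 in the mean of both alleles, or 7 and 1 when adjusted over the list alone. EXPA15 changed by -2.01 ± 0.11 in bin4-1 and -1.87 ± 0.11 in bin4-2 (SE). camera gave an adjusted p of 0.0131, lost at adjusted p = 0.489 with an estimated correlation. The histone, heat-shock and EXPA calls were also lost among genes with a mean log2 of at least 5, with adjusted p of 0.175, 0.133 and 0.133. Their medians there were 0.21, 1.29 and -1.42, against 0.22, 1.24 and -0.71 with all genes.

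bin4-2 differed from bin4-1 at 33 genes, 16 higher and 17 lower in bin4-2, a split that did not hold when a mutant array was left out. The pseudogene AT1G43590 was raised by 2.05 ± 0.13 in bin4-1 and stood at -0.22 ± 0.13 in bin4-2 against WT, a difference of -2.27 ± 0.13 between the alleles (SE, limma adjusted p = 1.5e-05). QQS, a gene that affects leaf starch, was 2.48-fold lower in bin4-2 than in bin4-1 (log2 -1.31, adjusted p = 0.0017), at -0.02 in bin4-1 and -1.33 in bin4-2 against WT. The neighbouring jacalin-lectin genes AT1G52060 and AT1G52070 differed by -1.46 and -1.13, with values above WT in bin4-1 (0.46 and 0.54) and below it in bin4-2 (-0.99 and -0.58). AT3G47800, a galactose mutarotase-like gene, differed by -1.08.

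Genes higher in bin4-2 than in bin4-1 included several with a weaker fall. AT3G45160 differed by 1.09 ± 0.15 (SE, adjusted p = 0.0147), AT1G78020 by 0.86 and AT3G48420, a chloroplast sugar-phosphate phosphatase gene, by 0.86. AT3G29970 rose more in bin4-2, with a difference of 0.98. AT1G47400, an iron-deficiency peptide gene, stood at -0.44 in bin4-1 and 0.50 in bin4-2 against WT, a difference of 0.94 ± 0.12 (adjusted p = 0.00758). At an unadjusted limma p under 0.05, a threshold that unchanged genes pass at a rate of 0.05, 908 of the 13356 genes differed between the alleles. The count of 33 was 9 (3 higher and 6 lower) and 11 (1 and 10) without bin4-1 replicates 1 and 2, and 7 without bin4-2 replicate 1 (1 and 6) or 2 (0 and 7). It was 51 without either WT array, where the spread of the WT pair no longer enters, as with the compared groups alone. All 5 genes named here lost the call without bin4-2 replicate 2, with differences of 1.22 (AT3G45160), 0.92 (AT3G29970), 0.88 (AT1G47400), 0.86 (AT1G78020) and 0.75 (AT3G48420). The call was also lost for 4 of them without bin4-1 replicate 2 (0.91 for AT3G29970, 0.79 for AT1G47400, 0.81 for AT1G78020, 0.88 for AT3G48420). The same held for 4 without bin4-2 replicate 1 (0.97 for AT3G45160, 1.00 for AT1G47400, 0.86 for AT1G78020, 0.97 for AT3G48420) and for 2 without bin4-1 replicate 1 (0.91 for AT3G45160, 0.84 for AT3G48420). An intensity trend gave 127 genes, array weights 68, a mean log2 of at least 5 gave 52 and all probe sets 55.

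The pericentromeric windows addressed heterochromatin, since the arms beside centromeres are rich in it. In the windows, AT2G04039 (-3.52 ± 0.15, mean of both alleles, SE), MSRB6 (-3.44 ± 0.11), AT3G45160 (-3.15), AT3G46490 (-3.08) and AT2G10940 (-3.01) fell most. The calcium-binding genes AT3G47480 (4.60 ± 0.13) and AT5G39670 (4.30 ± 0.09), the receptor kinase gene AT1G35710 (4.26), AT5G39520 (4.06) and the subtilase SBT3.5 (4.04) rose most. Among those given here by locus number, AT2G04039, AT3G45160, AT3G46490, AT3G47480, AT5G39670 and AT5G39520 lie outside the narrower windows, in the outer part of the wide ones. The 2275 window genes were dim, with a median log2 of 3.07 against 4.68 for the other 10990 nuclear genes, and 34.4% were pseudogenes.

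Fisher's exact test counts genes as independent, although all were measured on the same arrays. Its p-values and intervals therefore do not measure the spread between arrays or plants. Window genes rose less often than other nuclear genes, 9.76% against 26.1% (Fisher's exact test, odds ratio 0.306, adjusted p = 3.49e-72). Taken over all nuclear genes they also fell less often, 26.1% against 29.1% (odds ratio 0.858, 95% interval 0.773 to 0.951, adjusted p = 0.00467). That lower rate of falls did not pass without bin4-2 replicate 1 (odds ratio 0.910, Fisher p = 0.0743), with an intensity trend (0.914, p = 0.0802) or without probe sets that may match several transcripts (0.903, p = 0.0605). The direction turned among protein-coding genes, of which 32.5% fell inside the windows and 29.4% outside (odds ratio 1.15, adjusted p = 0.0213). The gap was wider among those with a mean log2 of at least 5: 193 of 435 window genes (44.4%) fell against 1526 of 4865 others (31.4%, odds ratio 1.74, interval 1.42 to 2.14, adjusted p = 1.24e-07). In that set 30.1% rose inside the windows and 40.0% outside (odds ratio 0.647, adjusted p = 8.85e-05). With genes chosen by the midpoint of the WT and mutant means, a filter added after the results were seen, 47.1% fell inside and 33.6% outside (odds ratio 1.76, interval 1.44 to 2.16). In the narrower windows, 36.3% of all protein-coding genes fell, against 29.4% outside the wide windows (Fisher's exact test, odds ratio 1.37, adjusted p = 0.00107). There 8.35% rose, against 26.5% (odds ratio 0.253, adjusted p = 2.39e-25). Among protein-coding genes with a mean log2 of at least 5, the odds ratio of falls in the wide windows was 1.76 in bin4-1 and 1.72 in bin4-2 singly.

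Over all window genes the median log2 change was -0.13 against -0.07 outside. Its camera adjusted p of 0.0306 was lost at adjusted p = 0.325 with an estimated correlation, and at 0.147 after quantile normalization. Among genes with a mean log2 of at least 5 the difference of medians was -0.26 and passed at the preset correlation (camera adjusted p = 0.0433). An estimated correlation was not applied to that set. Without bin4-1 replicate 1 or bin4-2 replicate 2 the adjusted p was 0.059 and 0.0856, at differences of -0.0588 and -0.051.

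**Figure D3:**
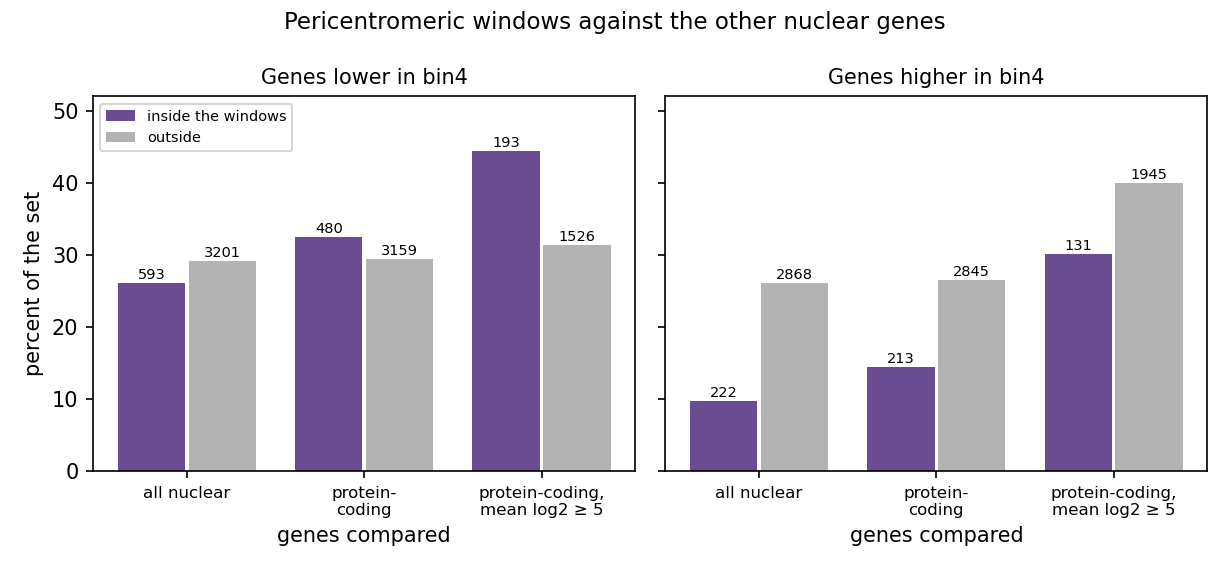
Percent of genes that fell (left) or rose (right) in the mean of both alleles, inside the pericentromeric windows (purple) and outside (grey), for 3 sets of nuclear genes; numbers above the bars count the genes. Among bright protein-coding genes 44.4% fell inside the windows and 31.4% outside.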

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

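The tests of RNA quality and hybridisation strength, and those of lists between the alleles with an estimated correlation, were chosen after the values they use had been seen; the list of further root markers and the tests on the windows were written before their results were seen.

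The arrays' control probe sets stand outside the gene tests. The 25S ribosomal RNA control was 1.58 higher on the log2 scale in the 4 mutant arrays than in the 2 WT arrays (9.50 to 10.2 against 7.84 and 8.57). The mean of 5 ubiquitin control sets was 0.91 higher. For both, an exact permutation test gave p = 0.0667, the smallest that 15 splits of the arrays allow.

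In a test of the difference itself, the alleles differed at 12 named genes. Values of bin4-2 minus bin4-1 were 0.79 for AT1G73600, 0.86 for AT1G78020, 1.09 for AT3G45160, 0.68 for AT2G36145, 0.98 for AT3G29970, 0.94 for AT1G47400 and 0.86 for AT3G48420. They were -2.27 for AT1G43590, -1.46 for AT1G52060, -1.31 for QQS, -1.13 for AT1G52070 and -1.08 for AT3G47800. In camera tests of the same difference, the photosynthesis list had a median of 0.30 (adjusted p = 0.00255), the flavonoid list 0.24 (0.0167), the histone list 0.16 (0.00127), plastid-encoded genes 0.091 (0.0366) and the 54 measured class III peroxidases -0.10 (1.28e-05). None of these 5 calls held with an estimated correlation, at adjusted p of 0.147, 0.306, 0.463, 0.909 and 0.463.

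About 47.0% of the tested genes differed between bin4-1 and WT and 47.7% between bin4-2 and WT. RNA degradation that differed between WT and mutants would move the 3' minus 5' difference of the control transcripts 1 way and strongly. The largest shift over actin, GAPDH and ubiquitin was -0.11 on the log2 scale and the shifts differed in sign, which argues against it, although each averages 2 probe pairs and single pairs shift more. For hybridisation strength, 2 of 2 WT arrays lay inside the range of the mutant arrays on the hybridisation spikes. The top of that range is bin4-2 replicate 1 alone, at a mean log2 of 8.71. The other mutant arrays lay at 7.56 to 8.02, below both WT arrays (8.68 and 8.11). The mutants minus WT gave -0.37 (exact permutation p = 0.4), so the spikes do not decide on hybridisation strength. The poly-A spikes, added before labelling, were 0.22 higher in the mutants, with both WT arrays below all 4 mutant arrays (exact permutation p = 0.133). The 25S ribosomal RNA and ubiquitin controls also separated both WT arrays from all 4 mutant arrays, at 1.58 and 0.91 higher in the mutants. A difference in labelling, RNA input or hybridisation is therefore not excluded. A different developmental stage was not tested and stays open beside the mutation of BIN4 itself.

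Bright protein-coding genes in the pericentromeric windows fell more often than the other bright genes. In 10000 sets of other genes matched on mean log2 value, 0% reached the observed share (44.4% against a matched mean of 31.6% and a highest of 39.1%). The mean level over the arrays therefore does not account for it. Most of the averaged arrays are mutant, however, and matching on the WT level was not done. The draws also took genes singly, so their spread leaves out changes that nearby genes share. With each chromosome left out in turn, the lower 95% bound of the odds ratio stayed at or above 1.28, so no single chromosome carries it. The share was higher inside the window of each chromosome, from 35.4% against 31.3% on chromosome 3 to 48.7% against 31.4% on chromosome 1. Spreading of heterochromatin in the mutants is a candidate explanation that these arrays cannot test, and a different makeup of the window genes, for example in chloroplast functions, stays open as well.

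As lists, class III peroxidases, many of them expressed in roots, were lower and photosynthesis genes higher in bin4-2 than in bin4-1 at the preset correlation only (adjusted p = 0.463 and 0.147 with an estimated correlation), while PRK, RCA, SBPASE and PORB did not pass singly (adjusted p = 0.281, 0.311, 0.491 and 0.917) and PORB stood at -0.11. A lower share of root tissue in the bin4-2 samples predicts lower values of further root markers. Of 48 such markers, 14 were measured, 13 of them lower in bin4-2, with a median of -0.20 against -0.01 for all genes (camera p = 6.47e-05, p = 0.0438 with an estimated correlation), though 0 passed singly by limma and the markers were also below WT in both alleles (medians -0.38 and -0.69). XTH26, the only marker in a list tested before, was the 1 not lower, and the 13 others had a median of -0.20 (p = 0.0378 with an estimated correlation). These values are consistent with a small difference in the share of root, and a difference between the alleles in root development stays open.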

How the results depend on the processing

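The alternatives were fixed before the data were examined, with these exceptions. Those on added lists, the split of the WT arrays and the midpoint filter were chosen after seeing the data. So were the list tests between the alleles with an estimated correlation. Among genes with a mean log2 of at least 5, where fewer genes are tested, 3927 genes changed in bin4-1, 3934 in bin4-2, 3656 in both and 52 between the alleles, 1 fixed list was called (the other 2 had fewer than 3 genes left and were not tested), and the odds ratio of falls in the windows turned to 1.81. In the genes above the median brightness that odds ratio was 1.76, and the window difference of medians was -0.23 (adjusted p = 0.0582). All probe sets, more tests by construction, gave 11846, 12031, 10673 and 55 genes, and the 2-fold threshold 1899, 1827, 1690 and 6. Between the alleles, an intensity trend gave 127 genes, array weights 68 and the compared groups alone 51. The window difference of -0.06 lost its call with an estimated correlation (-0.06, adjusted p = 0.325) and after quantile normalization (-0.0345, adjusted p = 0.147). In the narrower windows it was -0.0719 (camera adjusted p = 0.00777, and 0.379 with an estimated correlation). Of the added lists, 0 of 36 were called by camera with an estimated correlation, 2 of them at an unadjusted p under 0.05, and 34 by fry. The cause was not tested for the other shifts.

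Leaving out 1 array, with the lone array of its group assumed to vary like the others and adding no spread of its own, gave 4879 to 6172 genes in bin4-1, 5303 to 6003 in bin4-2, 4575 to 5257 in both and 7 to 51 between the alleles. The window difference was -0.0696 to -0.051 and was not called without bin4-1 replicate 1 or bin4-2 replicate 2. With the title suffix as a replicate block, 6221, 6335, 5548 and 25 genes passed. Deviations of arrays with the same suffix correlated at -0.003, 0.077 and -0.045 between groups, so across all genes the arrays share only a suffix. Of 69 plastid-encoded genes, however, 42 were higher on the array without the suffix in all 3 groups, and 0 lower in all. Among 126 pairs of named gene and comparison, no refit of a gene that kept all arrays ended a call, leaving one out ended 17, 11 values gained a call and 0 called values changed sign (AT4G32700, M17 and ICU2, not called with all arrays, did). Filters on dim genes removed 32 and 17 pairs, and 24 called pairs lie under 2-fold, which was applied to counts only. For lists, 5 values lost their call, all under filters on dim genes, and 172 did not change sides. That count leaves out the estimated correlation, which ended the flavonoid call and all 9 calls of added lists.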

Other observations

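The families described here were chosen after their values had been seen, and the neighbour test was written before. Several families not described so far held changed genes, in some of them in both directions, and none passed the camera threshold as a family. Of 20 beta-glucosidase genes (BGLU), 9 rose and 4 fell in the mean of both alleles, led by BGLU45 (3.49 ± 0.09, SE), BGLU25 (3.21) and BGLU46 (2.52), with a limma camera adjusted p of 0.103 for the family. Of 47 UDP-glycosyltransferases (UGT), 13 rose and 18 fell, and UGT73D1, UGT76B1 and UGT87A2 rose by 3.10, 3.03 and 2.78 (camera adjusted p = 0.752). The symbol group GH, which holds cellulase-type glycosyl hydrolases among others, had 8 falls and 2 rises, with GH9B13 at -2.21, GH9B8 at -2.06 and GH9C2 at -1.65 (adjusted p = 0.113).

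Of 12 ubiquitin-specific proteases (UBP), 6 rose and 0 fell, led by UBP18 (0.82 ± 0.09, SE), UBP22 (0.72) and UBP24 (0.62), with a camera adjusted p of 0.0915. Of 10 VPS genes of vesicle sorting, 5 rose and 2 fell, with VPS20.1 at 1.34, VPS60.1 at 1.30 and VPS60.2 at 1.16 (adjusted p = 0.103). Of 16 mitochondrion-encoded genes 6 rose and 0 fell, including nad4L (0.76) and cox1 (0.73), with an adjusted p of 0.0886. Adjusted over each list alone, the counts were the same for these families except for 4 mitochondrial rises. Peroxidases moved both ways, 18 up and 23 down of 54 (19 and 24 over the list alone), with a median of -0.17, a mean of 0.16 and a camera adjusted p of 0.821. After PRX52, AT5G06730 (3.66) and AT5G39580 (3.11) rose most. Of 113 cytosolic ribosomal protein genes 8 rose and 31 fell (8 and 29 over the list alone, adjusted p = 0.399), and of 989 pseudogenes 23 rose and 144 fell (16 and 41 over the list alone, adjusted p = 0.121). Over all 27 added lists that were not called, the adjusted p ran from 0.0886 to 0.878.

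A hypothesis written before its test was that neighbouring genes in the pericentromeric windows change together. Each bright protein-coding window gene was paired with the next such gene on its chromosome, so dim or unnamed genes can lie between them. Across 430 such pairs the log2 changes correlated at 0.163, above the highest of 1000 random orders of the same genes (0.153). The random orders also mixed genes of different chromosomes. Outside the windows, where a pair can also span a window, 4860 pairs correlated at 0.064, also above their highest random order (0.063). Genes that follow each other in this order may therefore share part of their change in both regions, although differences between chromosomes enter as well. Whether the difference between the regions exceeds chance, and how far tandem duplicates that share sequence contribute, was not tested. Genes are not independent replicates.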
